A study of Canis lupus familiaris with 18 samples.

How the data were processed

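Expression was measured in 18 libraries of dog MDCKI cells, 8 of the parental line and 10 of the line with bPAC. Per the labels' protocols, RNA was extracted with Lexogen's SPLIT kit and libraries were made with its QuantSeq 3' FWD kit, which sequences from near the 3' end of a transcript, so a gene's count does not scale with its length and depends on how well its 3' end is annotated. The genome build was CanFam3.1, per the submitters' processing notes. The aligner, the counting program and the annotation release are not given in the sources used here. The authors deposited 1 table of whole-number read counts per library, not normalised, with 32220 gene IDs and 5 rows for reads assigned to no gene.

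The 5 rows without a gene were kept out of library sizes and tests. Reads outside annotated genes made up 25.1% to 29.6% of all reads in a table, reads aligned to more than 1 place 37.5% to 44.4%, and reads assigned to genes 29.4% to 33.9%. In bPAC high light, reads aligned to more than 1 place made up 41.7% to 44.4%. They made up 38.5% to 39.9% in bPAC dark and 37.5% to 40.7% in bPAC low light. Reads outside genes made up 25.1% to 26.4% in bPAC high light, 27.6% to 28.2% in bPAC dark and 27.5% to 29.5% in bPAC low light. Whether these differences affect the comparisons with bPAC high light was not tested. Genes whose reads align equally well to a near copy lose those reads, and transcripts that end beyond their annotation count as outside genes, so levels of such genes are uncertain. Gene reads ranged from 2638511 to 9610144 per library, with a median of 4207160.5. Within groups, no pair of libraries agreed within sampling noise: chi-square per degree of freedom lay between 9.41 and 73.5 over 19 pairs. This argues against 1 library having been sequenced and deposited more than once, and each was counted as a replicate. It does not show that the replicates came from separate cultures. The libraries' labels give no batch, date or pairing.

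Groups were taken from the labels. All 18 libraries entered 1 model of 6 groups, which share an estimate of the spread because groups hold 2 to 4 libraries. Genes were filtered with filterByExpr at its default minimum count of 10, which kept 8530, libraries were scaled by TMM, and contrasts were tested with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested genes at 0.05. There were 10 contrasts, among them 3 interactions of line and light. Levels are CPM scaled by TMM, folds are edgeR's fitted values, and an SE is the absolute log2 fold change divided by the square root of the F statistic. Principal components used log2 CPM with a prior count of 2. The axis within groups is the first principal component of the same values after the group means were removed.

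The design, the alternatives and the rule for named genes were fixed before the data were examined. That rule asked for a gene symbol, for the 8 largest increases and decreases per contrast among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the libraries compared, and for further members of fixed lists. The files do not pair IDs with symbols and 0 of the 32220 IDs matched the reference table, so 32 gene lists with 737 genes, fixed before the data were examined, and the tests planned on them were not run. The rule was then changed, after a first look at the fitted model: the condition on symbols was dropped, and 2 genes per direction were named in each contrast. Biphasic genes were named as the 2 per direction with the smallest of the larger of both p-values.

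The script for the tests was checked on simulated counts with the real library sizes. Each gene had its mean over the groups in every library, and 200 of 8530 genes were changed. For low light in bPAC cells it recovered 34% of 2-fold and 84% of 4-fold changes, and for high light in parental cells 24% and 71%. In the real low light comparison of bPAC cells 3009 genes were called. The adjusted threshold is less strict there, so these shares need not hold for it. Unchanged groups were simulated 20 times to give the correlation that shared controls produce. All bPAC libraries, dark ones included, were drawn at the mean levels of the bPAC dark group, independently for each gene. Differences in reads without a gene and in the share of the 10 most abundant genes were tested between illuminated and dark libraries of each line by exact two-sided permutation, 6 tests in all, chosen after the data were seen. The sets of biphasic genes were tested in parental cells with fry and camera (limma 3.58.1), also chosen afterwards, with 6 tests each.

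Alternatives planned in advance were DESeq2's size factors, the DESeq2 1.42.0 test, limma-voom, no filter, a filter at a mean of 5 CPM, only the groups compared, and leaving out each library. Chosen after the data were seen were a surrogate variable from sva 3.50.0, the within-group axis as a covariate, libraries thinned to 2638511 reads, and 2 ways of leaving out libraries that lay far along that axis. The first of these, tried in exploration, left out bPAC low light 1 and 4, bPAC high light 2 and parental dark 3, which lie on the same side of the axis. It was replaced, in order not to pick a side, by leaving out the library farthest from its group mean in each group of 3 or more. The 5 libraries so left out, parental dark 3, bPAC dark 1, parental low light 1, bPAC low light 4 and bPAC high light 2, also all lie on that same side, and 3 of them are among the 4 left out first. Both ways are reported since their results differ, and neither is balanced over the axis. The spread of the correlation was taken from a jackknife over libraries, also chosen afterwards.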

Results

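Gene expression was profiled by 3' end sequencing in MDCKI cells, an epithelial line from dog kidney, and in MDCKI cells carrying bPAC, a bacterial adenylyl cyclase that makes cyclic AMP when illuminated with blue light. Cells of each line were kept dark or given a low or a high dose of light for 2 h, starting 16 h after plating in medium with 0.5% serum. The title of the series concerns a response of protein kinase A that turns as cyclic AMP goes up, and the comparisons address how transcript levels differ between the light doses and between the lines. There were 3 dark, 3 low light and 2 high light libraries of parental cells, and 3 dark, 4 low light and 3 high light libraries of bPAC cells.

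Reads assigned to genes ranged from 2638511 to 9610144 per library. The parental dark libraries held 9610144, 3308277 and 4134090 such reads, the parental low light libraries 3380458, 5264041 and 4334659, and the parental high light libraries 3988616 and 4004576. The bPAC dark libraries held 4370690, 2803728 and 3639812, the bPAC low light libraries 4280231, 4713423, 3442941 and 6836729, and the bPAC high light libraries 7153601, 4507783 and 2638511. Between 10617 and 12594 genes were detected per library, and 8530 passed the filter on low counts. The files name genes by Ensembl dog IDs and do not pair them with symbols, so genes are given by ID and genes are grouped by how they responded. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

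The first principal component of log2 normalised counts (CPM, counts scaled to a common library size) held 37.5% of the variance and the second 18.6%. On the second component every parental library scored above every bPAC library except bPAC low light 4, which scored 6.13 against 5.90 for parental dark 1. The dark libraries of bPAC cells scored from -52.0 to -31.8 on the first component, and the illuminated bPAC libraries from 6.70 to 67.2. The 4 bPAC low light libraries lay apart in pairs, with libraries 1 and 4 at 59.8 and 67.2 and libraries 2 and 3 at 10.99 and 15.1. The main axis of variation within groups held 29.8% of the variance left after the group means were removed.

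**Figure D1:**
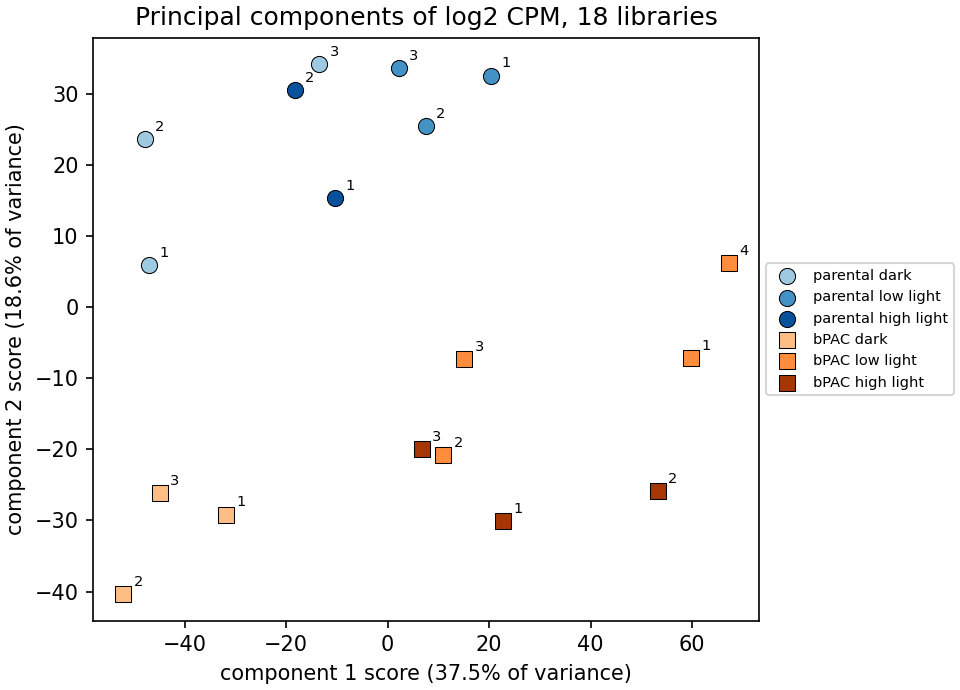
Scores of the 18 libraries on the first and second principal components of log2 CPM, in arbitrary units, with the share of variance on each axis. Circles are parental and squares bPAC libraries, shades give the light dose and digits the replicate; bPAC low light libraries 1 and 4 scored 59.8 and 67.2 on the first component and libraries 2 and 3 scored 10.99 and 15.1.

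In bPAC cells 3009 of the 8530 tested genes differed between low light and dark, 1468 higher and 1541 lower in low light. Of these, 749 rose and 996 fell by at least 2-fold. ENSCAFG00000017664 rose 7.02-fold (log2 fold change 2.81, SE 0.49), from 1.32 ± 0.952 CPM (SD, n = 3) to 8.92 ± 0.723 CPM (SD, n = 4), with an edgeR adjusted p of 0.000729. ENSCAFG00000040749 had 2 reads in the 3 dark libraries and 123 in the 4 low light libraries, or 6.32 ± 3.17 CPM (SD, n = 4; edgeR adjusted p = 0.000349). Among the genes that fell, ENSCAFG00000029442 went from 134 ± 64.1 CPM (SD, n = 3) to 6.97 ± 7.07 CPM (SD, n = 4; edgeR adjusted p = 0.00423). ENSCAFG00000011598 fell from 48.3 ± 5.37 CPM (SD, n = 3) to 2.88 ± 3.66 CPM (SD, n = 4; edgeR adjusted p = 0.00641).

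The count of genes called between low light and dark in bPAC cells was 1734 without bPAC dark replicate 2. It was 337 with 1 surrogate variable in the model, where 326 of the 3009 genes were still called and 3003 kept their sign, and neither ENSCAFG00000029442 (adjusted p = 0.135) nor ENSCAFG00000011598 (adjusted p = 0.272) was called. Across genes, which are not independent replicates, the low light fold changes correlated with the loadings of the within-group axis at r = 0.725. Reads counted as ambiguous were more frequent in illuminated than in dark bPAC libraries, at 0.0520 ± 0.00574 (SD, n = 7) against 0.0375 ± 0.00315 (SD, n = 3) per 100 gene reads (exact two-sided permutation p = 0.00833, the smallest these libraries allow, BH adjusted 0.05 over 6 tests).

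Between high light and dark 2097 genes differed in bPAC cells, 1083 higher and 1014 lower in high light. Of these, 463 rose and 787 fell by at least 2-fold. ENSCAFG00000009209 rose 16.5-fold (log2 fold change 4.05, SE 0.43), from 26.2 ± 6.02 to 434 ± 95.1 CPM (SD, n = 3 each; edgeR adjusted p = 5.11e-05), and stood at 166 ± 24.4 CPM (SD, n = 4) in low light. ENSCAFG00000039271 had 3 reads in the dark libraries and 72 in the high light libraries, or 5.84 ± 0.427 CPM (SD, n = 3; edgeR adjusted p = 0.00231). ENSCAFG00000011598, also lower in low light, fell from 48.3 ± 5.37 to 0.341 ± 0.0664 CPM (SD, n = 3 each; edgeR adjusted p = 0.00443). ENSCAFG00000010615 fell from 13.0 ± 3.68 CPM (SD, n = 3) to a level of 1 read in 3 libraries (edgeR adjusted p = 0.00478). The count was 1098 without bPAC dark replicate 2, 1385 without bPAC high light replicate 1 and 937 without bPAC high light replicate 2, and the fold changes correlated across genes with the within-group axis at r = 0.604. The 10 most abundant genes of each library took 18.05 ± 1.75% of its gene reads in illuminated bPAC libraries (SD, n = 7) and 14.6 ± 0.515% in dark ones (SD, n = 3; exact two-sided permutation p = 0.025, BH adjusted 0.05). In parental cells they took 13.7 ± 0.373% (SD, n = 5) and 13.6 ± 0.332% (SD, n = 3; exact two-sided permutation p = 0.679, BH adjusted 0.679).

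**Figure D2:**
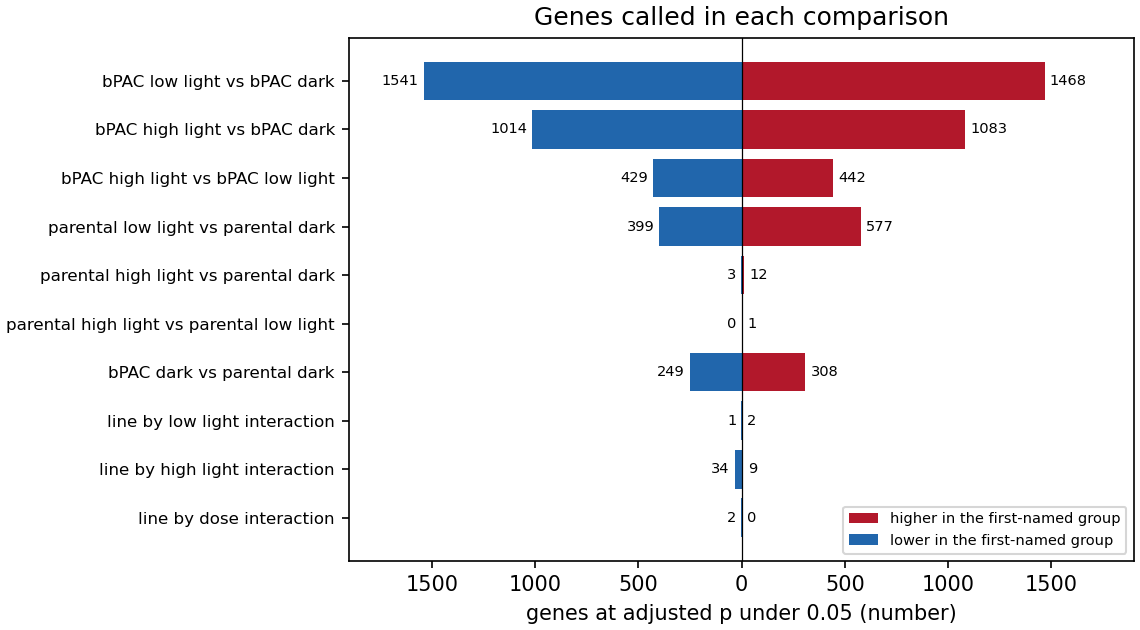
Number of genes called in each of the 10 comparisons at an edgeR adjusted p under 0.05, with genes higher in the first-named group to the right and genes lower to the left. The longest bars are those of bPAC cells in low light (1468 higher, 1541 lower) and the shortest that of parental high against low light (1 higher, 0 lower).

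The low and high light changes of bPAC cells went largely the same way. Of the genes called in each, 641 were higher and 715 lower at both doses, where independent lists of these sizes would share 186 and 183. Another 7 were higher in low and lower in high light, and 3 the reverse. The fold changes of the 8530 genes correlated at r = 0.775 (Spearman's rho 0.732). Simulated unchanged groups set against shared simulated dark libraries gave r = 0.545. The covariance was 0.753 against a simulated 0.0967, a difference of 0.656. Genes were drawn independently there, so the simulation lacks the within-group axis, with which the low and high light changes correlated at r = 0.725 and 0.604. Part of the difference from the simulation may come from that axis. The 3 shared dark libraries are too few to split, so part of the excess over independent lists may come from them.

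Between the doses themselves, 871 genes differed in bPAC cells, 442 higher and 429 lower in high than in low light. ENSCAFG00000016204 rose 13.3-fold, from 1.25 ± 0.869 CPM (SD, n = 4) in low light to 16.7 ± 5.45 CPM (SD, n = 3) in high light (edgeR adjusted p = 0.000158). ENSCAFG00000039271, at 6 reads in the 4 low light libraries, was higher in high light here too (edgeR adjusted p = 0.00279). ENSCAFG00000008929 fell 6.74-fold, from 6.33 ± 0.910 CPM (SD, n = 4) to 0.969 ± 0.236 CPM (SD, n = 3; edgeR adjusted p = 0.000755). ENSCAFG00000028434 fell 7.87-fold, from 8.50 ± 3.17 CPM (SD, n = 4) to 0.987 ± 0.990 CPM (SD, n = 3; edgeR adjusted p = 0.0138), and was not called without bPAC high light replicate 1. Leaving out bPAC low light replicate 4 gave 560 genes, bPAC high light replicate 1 gave 189, replicate 2 gave 515 and replicate 3 gave 555. A fit of only these 2 groups gave 273.

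A biphasic course, defined as a change from dark to low light and a change of opposite sign from low to high light, was called for 362 genes in bPAC cells. Of these, 208 were raised at the low dose and lowered again at the high dose, and 154 were lowered and then raised. By comparison, 34 genes were called in both steps with the same sign, 17 rising and 17 falling. Against the dark, the 208 genes had a median log2 fold change of 1.24 in low light and 0.10 in high light, and the 154 genes had medians of -0.85 and -0.02. At the high dose 9 of the 208 were called higher and 7 lower than in the dark, and 3 of the 154 were called higher. None of 20 simulations of unchanged groups gave a biphasic gene, but these called on average only 0.3 genes in low light, so that count could hardly be above 0. Over all 8530 genes, called or not, the signs of the 2 steps, which share the low light libraries, were opposite for 64.3%, against 63.6% (SD 0.514, n = 20 simulations) with unchanged groups.

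ENSCAFG00000014067 stood at 31.8 ± 1.92 CPM (SD, n = 3) in dark bPAC cells, 84.8 ± 11.6 CPM (SD, n = 4) in low light and 32.1 ± 1.63 CPM (SD, n = 3) in high light (edgeR adjusted p = 0.000189 and 0.000274 for the 2 steps). ENSCAFG00000018150 followed the same course at 28.2 ± 2.15, 68.8 ± 8.91 and 22.2 ± 2.77 CPM (SD, n = 3, 4 and 3). In the opposite course, ENSCAFG00000013369 went from 129 ± 11.1 CPM to 76.9 ± 4.11 CPM and back to 139 ± 6.16 CPM (SD, n = 3, 4 and 3), and ENSCAFG00000006100 from 325 ± 148 CPM to 98.1 ± 44.6 CPM and 308 ± 80.6 CPM. The number of biphasic genes was 216 without bPAC low light replicate 1, 180 without replicate 4, 62 without bPAC high light replicate 1 and 182 without replicate 3. It was 101 with only the groups compared in each fit, 68 with 1 surrogate variable, and 125 or 54 when libraries far along the within-group axis were left out in either of 2 ways.

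In parental cells, which carry no light-activated cyclase, 976 genes also differed between low light and dark, 577 higher and 399 lower in low light. ENSCAFG00000022737 rose 9.71-fold, from 0.567 ± 0.488 to 5.26 ± 1.57 CPM (SD, n = 3 each; edgeR adjusted p = 0.000915), and ENSCAFG00000022716 rose 6.23-fold, from 2.86 ± 1.21 to 18.9 ± 9.25 CPM (edgeR adjusted p = 0.000315). ENSCAFG00000032101 fell 10.6-fold, from 6.66 ± 1.92 to 0.633 ± 0.257 CPM (edgeR adjusted p = 0.00886), and ENSCAFG00000005345 fell 7.56-fold, from 5.21 ± 2.45 to 0.721 ± 0.3995 CPM (edgeR adjusted p = 0.00636); neither was called without parental low light replicate 2. Of the 577 genes raised here, 492 were also higher in low light in bPAC cells, and 325 of the 399 lowered genes were also lower there. Independent lists would share 99.3 and 72.1. No gene was called in opposite directions, and the fold changes of the lines, which share no library, correlated across genes at r = 0.750. The count was 242 without parental dark replicate 2, 268 without parental low light replicate 2 and 634 without parental low light replicate 1, and the fold changes correlated with the within-group axis at r = 0.503. Ambiguous reads per 100 gene reads were 0.0536 ± 0.00600 (SD, n = 5) in illuminated and 0.0367 ± 0.00375 (SD, n = 3) in dark parental libraries (exact two-sided permutation p = 0.0179, BH adjusted 0.05).

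Between high light and dark 15 genes differed in parental cells, 12 higher and 3 lower in high light, and 1284 genes had an unadjusted p under 0.05. If no gene differed, a share of about 0.05 of the 8530 tested genes would have such a p. The same holds for the other unadjusted counts below. ENSCAFG00000006164 rose 7.42-fold (log2 fold change 2.89, SE 0.29), from 126 ± 4.73 CPM (SD, n = 3) to 931 ± 341 CPM (SD, n = 2; edgeR adjusted p = 2.03e-05). It was the 1 gene called between high and low light in parental cells, 4.15-fold above 224 ± 28.2 CPM (SD, n = 3; edgeR adjusted p = 0.00567), but not without parental low light replicate 1 or parental high light replicate 1. The count between high and low light was 0 without parental low light replicate 1, 2 without parental low light replicate 3 and 3 without bPAC low light replicate 4. ENSCAFG00000000640 stood at 57.2 ± 49.1 CPM (SD, n = 2) in high light and 5.64 ± 0.00991 CPM (SD, n = 3) in the dark (edgeR adjusted p = 0.0142). ENSCAFG00000018917 fell 2.74-fold, from 355 ± 73.1 to 130 ± 43.3 CPM (SD, n = 3 and 2; edgeR adjusted p = 0.0218), and neither it nor ENSCAFG00000000640 was called without parental dark replicate 2 or 3 or parental high light replicate 2. ENSCAFG00000015499 fell 3.75-fold at an edgeR adjusted p of 0.0491, which was lost on leaving out any of 14 of the 18 libraries. The count of 15 rests on 2 high light libraries. It lay between 2 and 37 on leaving out 1 library and moved by over 1.5 times for 17 of the 18, the exception being bPAC high light replicate 3. DESeq2 called 151 genes between high light and dark and 51 between high and low light, and limma-voom 4 and 1; 1080 genes had an unadjusted p under 0.05 between high and low light.

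The genes with a biphasic course in bPAC cells were followed in parental cells, a comparison chosen after the data were seen. In parental low light the 208 genes had a median log2 fold change of 0.72, with 95.2% above 0 and 77 called higher, and the 154 genes had a median of -0.63, with 99.4% below 0 and 60 called lower. From low to high light the medians were -0.67 and 0.46, with no gene called on its own. Each of these 4 shifts passed a rotation test of the set (fry, p = 0.000154 and 0.000188 for low light, 0.00305 and 0.00358 for high against low) and a camera test against the other genes (adjusted p = 0.0375 with an estimated correlation). The low light and the high against low shifts share the 3 parental low light libraries, so a deviation of those libraries alone gives both with opposite signs, and they are not independent results. Against the dark, the medians in parental high light were 0.15 and -0.14, which did not pass the threshold (limma's fry, adjusted p = 0.316 for each). The directions were not particular to biphasic genes. All 1468 genes called higher in bPAC low light had a parental low light median of 0.63, with 94.8% above 0. For all 1541 called lower it was -0.73, with 95.5% below 0. From low to high light in parental cells these lists had medians of -0.39 (85.0% below 0) and 0.39 (83.6% above 0).

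**Figure D3:**
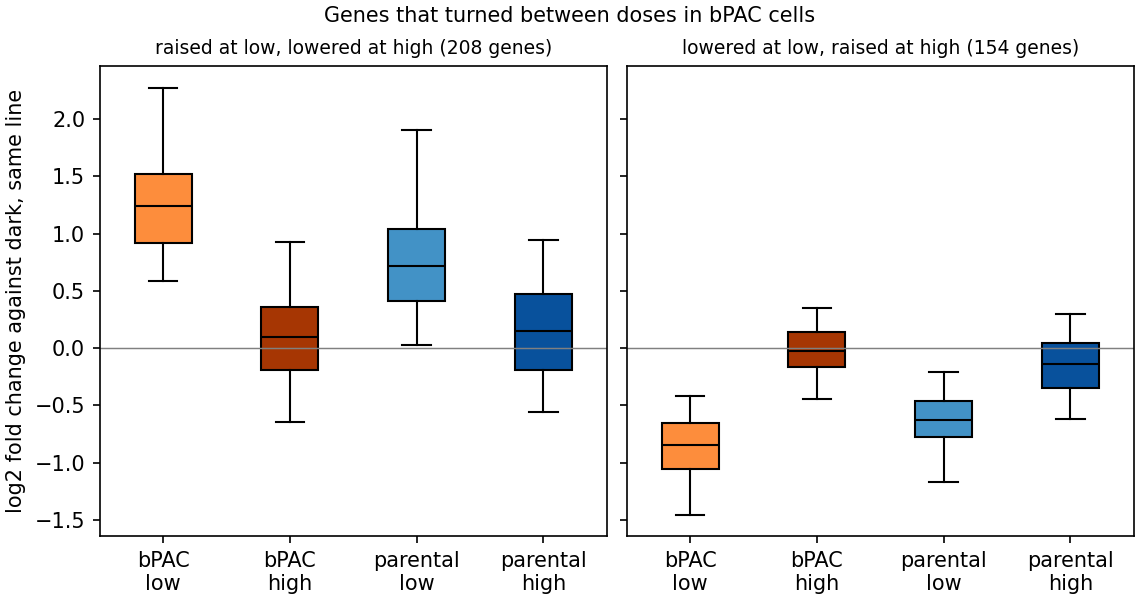
Log2 fold changes against the dark libraries of the same line for the 208 genes raised and then lowered (left) and the 154 genes lowered and then raised (right) in bPAC cells. Boxes span the quartiles with the median as a line and whiskers reach the 5th and 95th percentiles; the medians in parental low light are 0.72 and -0.63, and the bPAC values were used to choose the genes.

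In the dark, 557 genes differed between the lines, 308 higher and 249 lower in bPAC than in parental cells. ENSCAFG00000017018 was 30.0-fold higher, at 29.2 ± 11.4 against 0.841 ± 0.411 CPM (SD, n = 3 each; edgeR adjusted p = 1.46e-06), and ENSCAFG00000017855 had 60 reads in the bPAC and 1 read in the parental dark libraries (edgeR adjusted p = 0.00169). ENSCAFG00000018999 was 5.83-fold lower, at 6.47 ± 1.25 against 37.4 ± 2.94 CPM (edgeR adjusted p = 1.64e-06). ENSCAFG00000012619 was 13.2-fold lower, at 1.71 ± 0.940 against 21.4 ± 16.4 CPM (edgeR adjusted p = 0.00937), and was not called by limma-voom (adjusted p = 0.0743). The count was 238 without parental dark replicate 2, 224 without parental dark replicate 3 and 238 without bPAC dark replicate 2.

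Whether light acted differently in the lines was tested with interaction terms. At the low dose 3 genes passed, with 507 at an unadjusted p under 0.05. A share of about 0.05 of the 8530 tested genes would fall there if the lines responded alike. ENSCAFG00000016984 went from 80.8 ± 4.54 CPM (SD, n = 3) to 458 ± 109 CPM (SD, n = 4) in bPAC cells and from 73.1 ± 17.0 to 99.5 ± 19.6 CPM (SD, n = 3 each) in parental cells (edgeR adjusted p = 0.0113). ENSCAFG00000018583 went from 602 ± 61.1 to 1260.3 ± 186 CPM in bPAC cells and from 951 ± 158 to 699 ± 75.8 CPM in parental cells (edgeR adjusted p = 0.0182). ENSCAFG00000006638 went from 75.9 ± 5.93 to 14.3 ± 3.89 CPM in bPAC cells and from 19.8 ± 7.57 to 24.1 ± 1.26 CPM in parental cells (edgeR adjusted p = 0.00296). ENSCAFG00000016984 was not called without parental dark replicate 3, bPAC dark replicate 2 or 3, or parental low light replicate 2, and ENSCAFG00000018583 was lost without any of the same 4 libraries and also without parental dark replicate 2 or parental low light replicate 3. The count was 6 without parental dark replicate 1 and 1 without parental dark replicate 3, bPAC dark replicate 2 or 3, or parental low light replicate 2. DESeq2 called 12 genes and limma-voom 3.

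At the high dose the interaction passed for 43 genes, 9 with a higher and 34 with a lower response in bPAC cells. The 34 genes had a median log2 fold change of -1.78 in bPAC and 0.27 in parental cells, and the 9 genes had medians of 2.06 and -0.31. The genes were chosen by this difference between the lines, which favours opposite signs. All 1014 genes called lower in bPAC high light had a parental high light median of -0.51. For all 1083 called higher it was 0.39. ENSCAFG00000016285 went from 1.53 ± 0.832 to 10.5 ± 2.36 CPM (SD, n = 3 each) in bPAC cells and from 6.00 ± 1.37 CPM (SD, n = 3) to 2.77 ± 0.694 CPM (SD, n = 2) in parental cells (edgeR adjusted p = 0.00429). ENSCAFG00000030354 went from 17.3 ± 2.54 to 1.16 ± 0.554 CPM in bPAC cells and from 10.9 ± 1.70 to 17.2 ± 0.330 CPM in parental cells (edgeR adjusted p = 0.00126). ENSCAFG00000016204 (edgeR adjusted p = 0.041) and ENSCAFG00000001254 (edgeR adjusted p = 0.0339) also passed, and both lost the call without parental dark replicate 2 or 3, bPAC dark replicate 3, either parental high light library, or bPAC high light replicate 1 or 2. The former was also lost without bPAC dark replicate 1 or parental low light replicate 2, and the latter without bPAC dark replicate 2, bPAC low light replicate 1 or bPAC high light replicate 3. The count was 84 without parental dark replicate 1 and 68 without bPAC low light replicate 4. It lay between 17 and 27 without parental dark replicate 2 or 3, bPAC dark replicate 2 or 3, either parental high light library, or bPAC high light replicate 1 or 2. DESeq2 called 99 genes and limma-voom 35.

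The change from low to high light differed between the lines for 2 genes, both lower in bPAC cells. ENSCAFG00000000406 went from 177 ± 24.9 CPM (SD, n = 4) in low to 27.8 ± 1.89 CPM (SD, n = 3) in high light in bPAC cells, and from 225 ± 14.7 CPM (SD, n = 3) to 172 ± 31.0 CPM (SD, n = 2) in parental cells (edgeR adjusted p = 0.00455). ENSCAFG00000016464 went from 35.8 ± 5.30 to 10.6 ± 2.20 CPM in bPAC cells and from 38.1 ± 2.57 to 44.1 ± 3.12 CPM in parental cells (edgeR adjusted p = 0.00455). Of the 362 biphasic genes, 1 passed this test of the difference between lines. An unadjusted p under 0.05 was found for 592 genes, and DESeq2 called 40 and limma-voom 2. The count was 4 without parental dark replicate 1, parental dark replicate 3 or bPAC low light replicate 4, 8 without parental high light replicate 2 and 6 without bPAC high light replicate 3. In simulated data these interaction tests recovered 9%, 5% and 8% of 2-fold changes and 51%, 42% and 57% of 4-fold changes at the low dose, at the high dose and between doses.

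**Figure D4:**
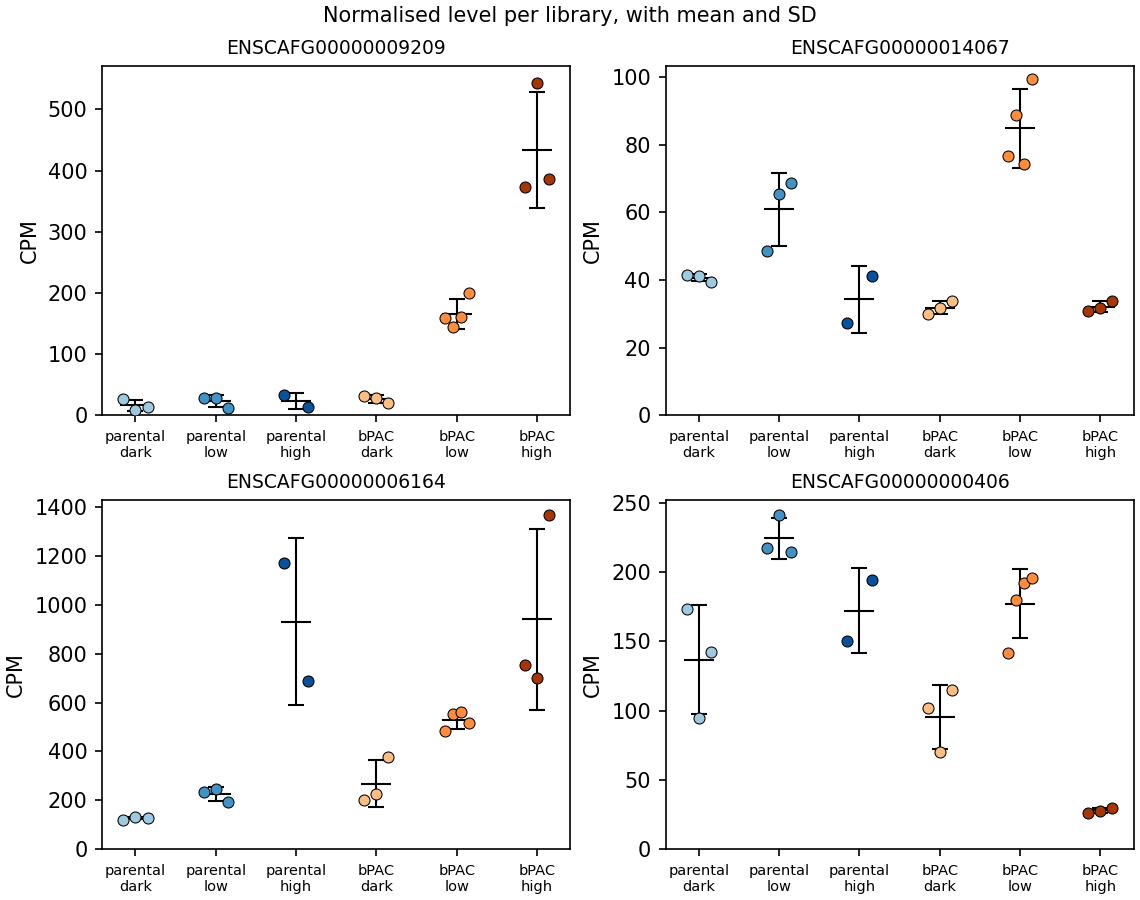
Normalised level in CPM per library for 4 genes, with points for libraries, a dash for the group mean and bars for the SD. ENSCAFG00000009209 stood at 26.2, 166 and 434 CPM in dark, low and high light in bPAC cells, ENSCAFG00000014067 at 31.8, 84.8 and 32.1 CPM, ENSCAFG00000006164 at 126, 224 and 931 CPM in parental cells, and ENSCAFG00000000406 at 27.8 CPM in bPAC high light; the 4 were picked for the plot after their values were seen.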

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

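Of the tests weighed here, that on the 10 most abundant genes and the counts of other splits were set before their result was seen; those on the within-group axis, the surrogate variable, thinning, unlit libraries and light or handling were chosen only afterwards.

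Genes with a biphasic course in bPAC cells moved the same way in parental cells, which have no light-activated cyclase. In parental low light all 1468 genes called higher and all 1541 called lower in bPAC low light had medians of 0.63 and -0.73. The pattern is thus not particular to biphasic genes. With the surrogate variable in the model the median parental low light log2 fold change was 0.64 for the genes raised and then lowered (quartiles 0.35 and 1.00, 0.72 without it). For the genes lowered and then raised it was -0.55 (quartiles -0.70 and -0.41, -0.63 without it). This does not decide whether the within-group axis is a cause. Across libraries the surrogate correlated with that axis at r = 0.707. Its means in parental dark and low light were -0.0946 and 0.0210 (SD 0.114 and 0.128, n = 3 each), against -0.209 and 0.252 in bPAC cells. It could therefore move the parental medians little. After thinning to equal depth 92.8% of the genes raised and then lowered stayed above 0, which argues against depth. Light itself, acting without bPAC, and handling or position shared by wells of the same dose cannot be told apart: both predict that the lines move together, as they did (r = 0.750 across genes), and the labels name no plate, day or mock illumination. A light response that does not need bPAC therefore stays a hypothesis. In parental high light the medians of the biphasic sets against the dark were only 0.15 and -0.14. The step from low to high light passed fry (adjusted p = 0.00537 for each set). A light response that only grows with dose would not shrink in this way, but parental high light rests on 2 libraries. A deviation of the 3 parental low light libraries alone would also give this course.

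The count for low light in bPAC cells went from 3009 to 337 with a surrogate variable. Of that variable's variance, 45.8% lay between groups, so it removes part of any light effect along with other variation, and the median of the genes raised and then lowered went from 1.24 to 0.90 in bPAC low light. Depth as the source of the within-group axis is argued against by library scores that correlated at 0.997 before and after thinning. Unequal light reaching wells of a group stays open: the main axis of the 3 unlit parental libraries correlated across genes at 0.544 with the low light change in bPAC cells, but 3 libraries give this value no spread. A covariate independent of the groups gave 3620 genes, but such a covariate removes only spread within groups and nearly fixes that outcome, so this test was set aside as uninformative, and how much of the count reflects light and how much the shared axis stays open.

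Interactions of line and light passed for 3 genes at the low dose, 43 at the high dose and 2 between doses, each a tested difference between the lines. Of the 43, 34 were lower in bPAC cells. Leaving out the 10 most abundant genes before scaling gave 41 called genes with 78.0% of them lower. Thinning gave 40, 35 of them among the 43, with 77.5% lower. The share after thinning argues against depth as the cause of that direction. TMM scaling already trims the most abundant genes, so leaving 10 of them out could change little. The share without them therefore does not decide whether a few genes taking most counts are the cause. Whether bPAC or another feature of the lines underlies these differences was not tested.

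Other splits of the libraries bear on whether chance gives such counts. For low light in bPAC cells 1 of 35 splits, the real one, gave as many as 3009 genes (highest other 2370, median of the others 0). The split with 2370 put the dark libraries together with bPAC low light 2, and so kept much of the light contrast. For high against low light 1 of 35 gave as many as 871 (highest other 458, median 0). A share of 1 in 35 is the smallest these splits allow. It argues against a chance division of the libraries for both counts as fitted on all libraries. It does not bear on a cause shared by the libraries of a group, such as handling. The count of 871 was 189 without bPAC high light replicate 1 and 273 with only both groups fitted, and no splits were counted under those settings. The split with 458 put bPAC low light 1 and 4 together with bPAC high light 2, the libraries of these groups with high scores on the within-group axis. For high light in bPAC cells (2097, highest other 0), low light in parental cells (976, highest other 9) and the lines in the dark (557, highest other 0), 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. For the low dose interaction 4 of 100 splits of the light labels within lines gave at least 3 genes (highest other 2153), which leaves chance open for the 3 genes. Such splits break up or keep the light effects of each line: the split with 2153 moved only parental libraries and left every bPAC label as it was.

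A value far from the rest was sought in 46 library measures and named genes within the 4 bPAC low light libraries. All other groups hold fewer than 4 libraries and were not screened. The 46 share the same libraries and are not independent. Of them 4 stood out, where chance gives about 1 in 20. They were ENSCAFG00000016204 at 2.54 CPM in bPAC low light 2, ENSCAFG00000008929 at 4.98 CPM in bPAC low light 3, ENSCAFG00000018583 at 1536 CPM in bPAC low light 1 and ENSCAFG00000013369 at 70.8 CPM in bPAC low light 3. Among reads assigned to no gene, ambiguous reads stood above the dark libraries in both lines under light, at 0.0536 per 100 gene reads in parental and 0.0520 in bPAC cells. Reads outside genes stood at 92.4 ± 3.20 per 100 gene reads in illuminated parental libraries (SD, n = 5) against 86.1 ± 1.90 in dark ones (SD, n = 3; exact permutation p = 0.0357, BH adjusted 0.0536). In bPAC cells they stood at 85.5 ± 3.79 (SD, n = 7) against 83.99 ± 2.22 (SD, n = 3; exact permutation p = 0.55, BH adjusted 0.66). Both light doses are pooled in these tests. Apart, bPAC low light stood at 88.1 ± 2.71 (SD, n = 4) and bPAC high light at 82.1 ± 0.879 (SD, n = 3). Their libraries did not overlap (85.2 to 91.3 and 81.1 to 82.8). Parental low and high light stood at 94.1 and 89.9. The value was thus highest in low light in both lines, and a difference between doses was not tested.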

How the results depend on the processing

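The surrogate variable, the axis covariate, thinning and both ways of leaving out distant libraries were chosen after the data were seen. No result reversed. Of 1204 checks of 42 gene results, 1119 kept their side of the threshold and 85 lost it, 54 of them on leaving out 1 library. These genes were picked because they were called, most of them without overlap between the libraries compared. No call could therefore be gained, and a reversal was hardly possible. Of the checks, 756 left out 1 library, often from a group outside the comparison. The tally thus does not measure how stable the results are. The cause was not tested for any change below, except that settings with fewer libraries have fewer samples. No paired analysis was possible because the labels give no replicate numbers: the numbers used here follow the order of accessions, only name libraries and tie none to another group. The planned list tests were not run for want of gene symbols. Apart from the ranges on leaving out 1 library and the last values for thinning, the values below are counts of genes that moved by over 1.5 times, for comparisons named by their first group where the other is the dark group of the same line, and correlations of low and high light fold changes in bPAC cells that moved by over their jackknife SE.

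With DESeq2's size factors parental high gave 7 genes. The DESeq2 test gave 151 for parental high, 51 for parental high against low, 12, 99 and 40 for the interactions and a correlation of 0.665. Limma-voom gave 4 for parental high. Without a filter parental high gave 227, parental high against low 52, the dark comparison 864, the interactions 76, 329 and 70 and the correlation 0.630. The filter at 5 CPM gave 6 and thinning 5 for parental high. With only the groups compared, bPAC high against low gave 273, parental high 2, the dose interaction 1 and biphasic genes 101. The surrogate variable gave 337 for bPAC low, 236 for parental high, 5 and 30 for the low dose and dose interactions, 68 biphasic genes and a correlation of 0.641. The axis covariate gave 1497 for bPAC high against low, 1812 for parental low, 225 and 69 for parental high and high against low, 1101 in the dark, 141, 461 and 27 for the interactions and 782 biphasic genes.

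Leaving out the farthest library of 5 groups gave 1064 for bPAC high, 243 for bPAC high against low, 3 and 0 for parental high and high against low, 187 in the dark, 0, 8 and 0 for the interactions and 125 biphasic genes. The set tried first, 4 libraries on one side of the axis, gave 1424 for bPAC low, 161 for bPAC high against low, 1746 for parental low, 329 for parental high, 308 in the dark, 7 for the dose interaction, 54 biphasic genes and a correlation of 0.695. Leaving out 1 library at a time gave 1734 to 3260 for bPAC low, 937 to 2357 for bPAC high, 189 to 899 for bPAC high against low, 242 to 1248 for parental low, 2 to 37 for parental high, 0 to 3 for parental high against low, 224 to 720 in the dark, 1 to 6, 17 to 84 and 2 to 8 for the interactions, 62 to 492 biphasic genes and correlations of 0.722 to 0.812 (jackknife SE 0.0716). Thinning to the smallest library gave 2686 genes for bPAC low and 264 biphasic genes. At the depth, spread and library numbers of these data, simulated 2-fold changes were recovered at 21% to 42% in comparisons within a line and at 5% to 9% in interactions; depth was not varied there.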

Other observations

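The tests here were chosen after the data were seen. A further 475 genes differed between high and low light in bPAC cells without a call between low light and dark. Of these, 271 were higher and 204 lower in high light, and 179 of the former and 115 of the latter were also called in the same direction against the dark. ENSCAFG00000009209, named for high light, also stood higher in low light in bPAC cells (6.31-fold, edgeR adjusted p = 0.000423) and rose 2.62-fold from low to high light (edgeR adjusted p = 0.0215), while in parental cells it stood at 16.0 ± 9.11, 22.7 ± 9.90 and 23.2 ± 13.4 CPM in dark, low and high light (SD, n = 3, 3 and 2), and the high dose interaction passed (edgeR adjusted p = 0.012).

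Fold changes of the 2 lines correlated across genes at r = 0.488 for high light and r = 0.750 for low light, and the difference between these correlations was not tested. Parental high light rests on 2 libraries, with a median SE of 0.348 against 0.310 for low light, which lowers a correlation. Low light changes also correlated with the within-group axis at r = 0.503 in parental and 0.725 in bPAC cells, against 0.230 and 0.604 for high light. A difference between doses can therefore not be read from these values. The changes from low to high light correlated between the lines at r = 0.368 (Spearman's rho 0.442).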
